A study of Mus musculus with 2 samples.

How the data were processed

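Polyadenylated RNA-seq of embryonic mouse liver at day 14.5 was analysed in 2 libraries, which the labels number as biological replicates 1 and 2 of 1 experiment. The labels describe each sample as the liver of a single animal and also as a pool of both sexes, and give both the same donor identifier. Whether the replicates are separate embryos or separate pools is therefore open, and the spread between them may be partly technical.

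Per the deposited notes beside the tables, each library was quantified from a transcriptome alignment on mm10 (GRCm38) with GENCODE annotation M4. The column names are those written by RSEM. The aligner, the counting program, their versions, the strand setting and any filters are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited gene and transcript tables hold expected counts, which are estimated and fractional where reads were shared among genes, and posterior mean counts. The deposited TPM columns, in maximum likelihood and posterior mean form, are scaled by the authors over all entries, including phiX174 and other entries that are not mouse genes. In the posterior mean form entries without reads hold values above 0. The deposited interval bounds, treated here as a score, lie on the posterior mean TPM scale, for Afp in replicate 1 from 97.7 to 127 where the TPM was 2075, and their level is not stated in the tables, so they are not used as errors of TPM. The deposited percent column gives each transcript's share of its gene's TPM. The effective length was the length minus 35 nt for all transcripts of 200 nt or more, which corresponds to a fragment length of 36 nt.

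The gene tables have 43346 mouse gene entries, 26248 entries with a number as identifier, 96 ERCC spike-in entries and phiX174. Gene symbols, biotypes and coordinates came from GENCODE M21 on GRCm38 by gene identifier, which matched 42462 entries and left 884 unmatched. Of transcripts with the same identifier and version in both annotations, 100% had the same length. Ahsp and Klkb1 were the list members not matched. Entries other than mouse genes stayed out of library sizes and tests; phiX174 took 33.4% and 32.4% of all counts, the numbered entries 0.432% and 0.352%, and mouse genes 66.2% and 67.2%. Protein-coding genes took 85.5% and 83.7% of mouse gene counts, and processed pseudogenes 3.58% and 7.50%. The depth of 63611 and 52862 counts sets the precision. A count of 0 was taken to allow up to 3 counts, a set floor. This is a share of 0.00713% of mouse gene counts in replicate 1 and 0.00844% in replicate 2. The floor is tighter than the two-sided 95% intervals used elsewhere, whose Poisson upper limit for a count of 0 is 3.69. The reads carry no molecular identifiers, so intervals and floors cover counting error only.

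The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. With 1 group there is no test between groups, and 2 values against 2 could not go below a two-sided exact p of 0.333. Expected counts were rounded to whole numbers for edgeR 4.0.16 (R 4.3.3), which gave TMM factors, filterByExpr with its default minimum count of 10, and the common dispersion of a 1-group design, reported as the biological coefficient of variation. Each filtered gene was tested between the 2 libraries with a two-sided exact conditional binomial test given the TMM-scaled library sizes, Benjamini-Hochberg adjusted at 0.05. Fold changes of genes are on counts scaled in this way, with 95% exact binomial intervals, and fold changes of lists are ratios of shares of mouse gene counts. For each list the number of members called adjusted over the list alone equalled the number over all genes tested. TPM was analysed as log2(TPM + 1). The gene lists covered globins of adult and embryonic type, heme synthesis, red cell membrane, late erythroid maturation, erythroid transcription factors, iron, blood cell lineages, hepatocyte functions, cholangiocytes, stellate cells, mesothelium, endothelium, cell cycle, cytokines and their receptors, immediate early genes, imprinted genes, histones, mitochondrially encoded proteins, sex markers, 7 other tissues and ribosomal proteins. Each list's median level was placed among 10000 random lists of the same size, and its median log2 ratio among 10000 lists matched on mean expression in 20 bins, as a description.

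Genes were named by a rule: the 25 of highest mean TPM with mitochondrial genes apart, the leading 4 members of each list and undetected members of cell type lists, all members of lists of 5 or fewer, both genes of each pair, the 10 called genes of largest TPM ratio in each direction with a mean of 5 TPM or more, and 10 genes by transcript share. For length, some genes of the rule were left out, high-ranked ones among them. Members chosen by counts in place of TPM, such as Ank1, Top2a or Apob, and genes named because a call was lost, were picked after their values were seen.

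TPM depended on which transcripts of a gene received the reads. Of the 216 genes with 10 or more counts in both libraries, 35 (16.2%) differed over 2-fold in effective length between the libraries, for Xist 17734 and 1183 nt, for Slc4a1 3284 and 559 nt and for Cdk4 437 and 1916 nt. In 44 (20.4%) the TPM ratio and the scaled count ratio had opposite signs. Only the counts were TMM-scaled, so genes near equality can differ in sign without a change in length. For mt-Co1 the log2 ratios of replicate 2 over replicate 1 were 0.0753 for TPM and -0.132 for counts. Counts and shares of counts were therefore given beside TPM, a choice made after the data were seen.

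The procedures were tested on simulated data with the real means and library sizes. With counting error alone, the binomial test called 28.1% of genes changed 2-fold, 83.6% of those changed 4-fold, 100% of those changed 8-fold and 0.946% of unchanged genes, over 620 genes. With a simulated coefficient of variation of 1, it called 59.0% of unchanged genes over 633 genes, so its calls measure the distance between libraries. Both runs tested genes of simulated mean count 10 or more with total counts as library sizes. Their rates do not apply to the 207 filtered genes tested with TMM-scaled sizes. At a mean count of 10 or more, the test on the data called 57.2% of 573 genes. A separate simulation with the same coefficient and no changed genes gave an estimate of 0.52 after filterByExpr (255 genes). It gave 0.985 with a mean count of 10 or more (653 genes), since filterByExpr on 2 libraries keeps genes high in both. Alternatives covered pseudocounts, count and TPM thresholds, posterior mean values, DESeq2 1.42.0 size factors and dispersions, total counts as library sizes, rescaled TPM, coding transcripts, shares by count, and each library left out. Alternatives added after the data were seen are named in the closing section. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.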

Results

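Polyadenylated RNA from the liver of C57BL/6NCrl mouse embryos (strain B6NCrl in the labels) at day 14.5 was sequenced in 1 group of 2 biological replicates. The fetal liver at this stage is the main site of red cell formation and is also growing hepatocytes. No other tissue, age or treatment was analysed here, so the comparisons lie within each library and between the replicates. Replicate 1 held 63611 expected counts and replicate 2 held 52862, of which 42104 and 35537 fell on mouse genes. A single read on a gene of 2000 nt was worth 9.67 TPM (transcript abundance scaled to a fixed sum per library) in replicate 1 and 12.4 TPM in replicate 2. Of 43346 gene entries, 7326 had reads in replicate 1 and 7808 in replicate 2, and 586 and 649 reached 10 counts. All intervals and upper limits given here cover counting error only.

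The adult-type globins Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, which encode the chains of haemoglobin, were the most abundant list in replicate 1. In replicate 2 they came after the ribosomal protein (2.82%), plasma protein (1.82%), cell cycle (1.73%) and red cell membrane (1.42%) genes by share of mouse gene counts, but by summed TPM (20535) only after the ribosomal protein genes (39673). The 4 globin genes summed to 114054 ± 132256 TPM (SD, n = 2). They took 13.9% of mouse gene counts in replicate 1 (95% Wilson interval 13.6 to 14.2) and 1.37% in replicate 2 (1.25 to 1.5), a 10.2-fold higher share in replicate 1 (9.25 to 11.2). With counts scaled in 7 ways, the fold of replicate 1 over replicate 2 ran from 4.87 to 12.7. Without Hba-a1 the shares were 6.61% and 1.36%. The embryonic-type globins were far lower, with 20 counts in replicate 1 and 8 in replicate 2 over Hba-x, Hbb-y and Hbb-bh1, and no count for Hbb-bh2.

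Within the alpha-globin locus on GRCm38 chromosome 11, Hba-a1 (ENSMUSG00000069919.7, 32283511 to 32284465, plus strand) had 3076 counts in replicate 1 and 4.23 in replicate 2, and Hba-a2 (ENSMUSG00000069917.7, 32296489 to 32297298, plus strand) had 875 and 12.8. In the beta-globin locus on chromosome 7, Hbb-bs (ENSMUSG00000052305.5, 103826534 to 103828096, minus strand) had 1582 and 255 counts and was 5.60-fold higher in replicate 1 (95% interval 4.91 to 6.42). Hbb-bt (ENSMUSG00000073940.3, 103812524 to 103813996, minus strand) had 325 and 215 counts, 1.37-fold higher in replicate 1 (1.15 to 1.63). In the exact binomial test between these 2 libraries, 3 of the 3 globins that passed the count filter were called, all higher in replicate 1, with Benjamini-Hochberg adjusted p = 2.27e-218 for Hba-a2, 3.07e-203 for Hbb-bs and 0.00234 for Hbb-bt. Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so the split within each pair is uncertain. Hba-a1 did not pass the filter because of its low count in replicate 2. The direction for Hbb-bt was the opposite with scaling factors taken from the 25 genes of mean count 100 or more, as it was by construction for every gene under 2.23-fold higher in replicate 1.

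Apart from the embryonic-type globins with their few counts, other erythroid groups took a higher share in replicate 2 or similar shares in both libraries. The similar shares of iron handling genes rested on Tfrc, as given below. Red cell membrane and cytoskeleton genes (18 members) took 0.963% of mouse gene counts in replicate 1 and 1.42% in replicate 2, 1.47-fold higher in replicate 2 (1.29 to 1.68). The ratio was 1.18 with scaling factors from unfiltered genes and 1.21 with those from genes of mean count 10 or more. Slc4a1, the band 3 anion exchanger (ENSMUSG00000006574.11, chromosome 11, 102348824 to 102366203), had 90 and 132 counts, Epb41 had 25 and 77, and Ank1 had 29 and 61. These 3 of 8 tested members were called higher in replicate 2 by the exact binomial test, but with no filter on low counts the calls on Slc4a1 (adjusted p = 0.262) and Ank1 (adjusted p = 0.0587) were lost, while Epb42 (1 and 28 counts, exact adjusted p = 1.72e-05) was gained. Ermap had 88 and 70 counts. Heme synthesis genes took 0.226% and 0.465%, 2.06-fold higher in replicate 2 (1.59 to 2.68), or 1.65-fold and 1.70-fold with those 2 scalings. Cpox was the 1 called member of 4 tested, at 13 and 33 counts. The Cpox call was also lost with no filter, at an exact adjusted p of 0.148, while Urod (2 and 20 counts, 0.00726) and Ppox (8 and 29 counts, 0.0366) were gained. Alas2, the erythroid form of the enzyme that starts heme synthesis, had 15 and 15.9 counts. Late erythroid maturation genes took 0.916% and 1.18%, 1.29-fold higher in replicate 2 (1.12 to 1.48), but 1.03-fold with scaling factors from unfiltered genes and 1.06-fold with those from genes of mean count 10 or more. Without Bnip3l, at 1.15 and 68.7 counts, they took 0.913% and 0.988%, a ratio of 1.08 (0.934 to 1.25). Of 7 tested members, Prdx2 was called higher in replicate 2 (48 and 107 counts) and Car2, a carbonic anhydrase, higher in replicate 1 (79 and 33 counts), a direction that turned with the 25-gene scaling. Bnip3l was called with no filter (exact adjusted p = 1.58e-16).

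Erythroid transcription factors took 0.333% of counts in replicate 1 and 0.340% in replicate 2, and their summed level was 1653 ± 175 TPM (SD, n = 2). Lmo2 had 7 and 21 counts, Klf1 had 14 and 8, and Gata1 had 19 and 2. Neither of the 2 members that passed the filter was called, but with no filter Gata1 was called, 8.58-fold higher in replicate 1 (exact binomial adjusted p = 0.00578). Iron handling genes took 0.852% and 0.805%, or 0.749% and 0.422% without Tfrc. Tfrc, the transferrin receptor (ENSMUSG00000022797.11, chromosome 16, 32608920 to 32632794), had 43 and 136 counts and was 3.50-fold higher in replicate 2 (2.47 to 5.06), the only called member of 3 tested (exact binomial adjusted p = 1.39e-13). Ftl1, a ferritin light chain, had 83.4 counts in replicate 1 and 0 in replicate 2, and with no filter it was called, as was Slc40a1, the iron exporter ferroportin (22 and 3 counts), at exact adjusted p of 9.00e-24 and 0.00403.

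**Figure D1:**
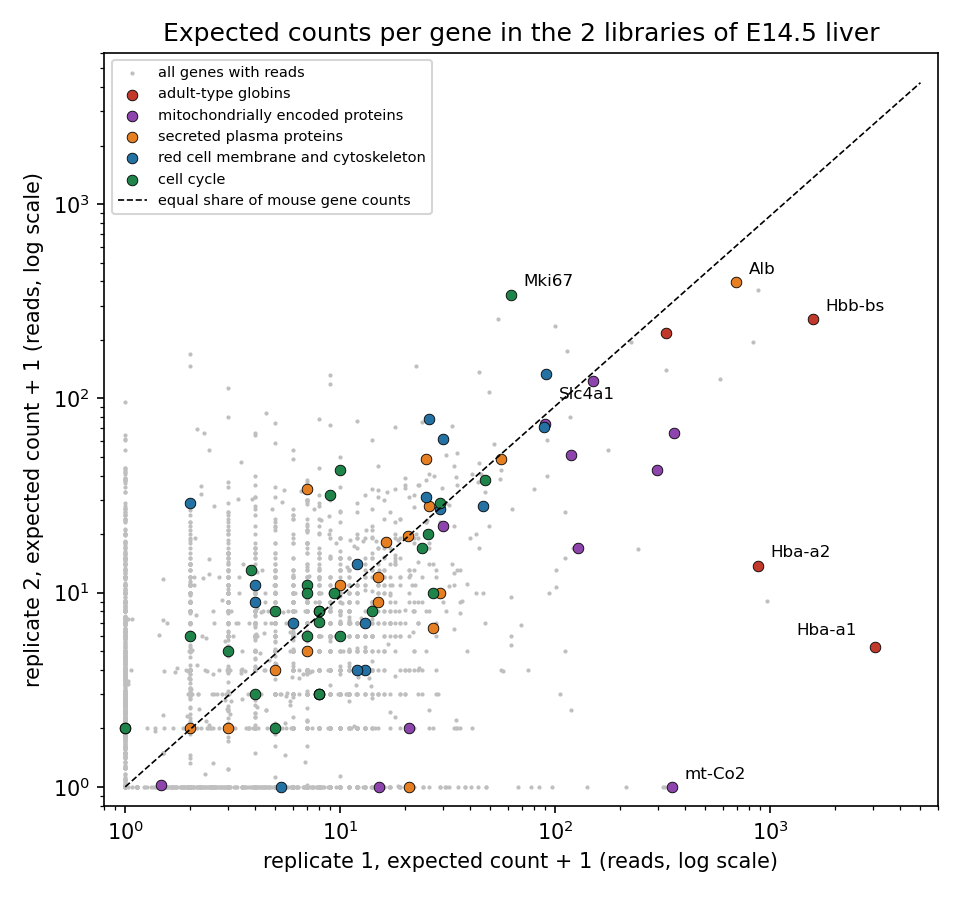
Expected counts plus 1 of each gene with reads in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale); each point is a gene, colours mark 5 gene lists and the dashed line marks equal shares of mouse gene counts. Hba-a1 lies far to the right, at 3076 and 4.23 counts, and Mki67 lies above the line, at 61 and 341.

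By counts over both libraries, the hepatocyte lists were led by Alb, which encodes serum albumin, and Afp, its fetal relative alpha-fetoprotein. By mean TPM, H19 of the hepatoblast list lay above Afp, at 2495. Alb (ENSMUSG00000029368.9, chromosome 5, 90460897 to 90476602, plus strand) was at 5679 ± 1253 TPM and Afp (ENSMUSG00000054932.3, chromosome 5, 90490737 to 90508907, plus strand) at 2187 ± 159 TPM (SD, n = 2). Alb exceeded Afp 3.16-fold in replicate 1 (95% counting interval 2.72 to 3.70) and 2.08-fold in replicate 2 (1.75 to 2.49). The log2 ratio of Afp over Alb was -1.36 ± 0.43 (SD, n = 2). Afp had 224 and 194 counts and was not called between the libraries (1.04-fold, 0.857 to 1.27, exact binomial adjusted p = 0.999). Alb had 694 and 396 counts and was 1.58-fold higher in replicate 1 (1.40 to 1.80, exact binomial adjusted p = 1.43e-12), a direction that turned with the scaling from the 25 most abundant genes.

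Secreted plasma protein genes (22 members) took 2.30% of counts in replicate 1 and 1.82% in replicate 2 and summed to 10557 ± 250 TPM (SD, n = 2). Without Alb they took 0.655% and 0.707%. Alb and Serpina6 (24 and 48 counts) were called among 7 tested members, in opposite directions, and the Serpina6 call was lost with no filter (exact adjusted p = 0.204). The members gained with no filter were Ambp, at 6 and 33 counts, and Rbp4, Serpina1a and Serpina1c, which were higher in replicate 1. Trf, which encodes transferrin, had 54.7 and 48 counts. Hepatoblast and fetal growth genes took 1.17% and 1.32%, or 0.937% and 0.656% without H19. The imprinted neighbours H19 and Igf2, which share an imprinting control region, went in opposite directions. H19 (ENSMUSG00000000031.11, chromosome 7, 142575529 to 142578143, minus strand), a noncoding RNA, had 98.4 and 236 counts and was 2.67-fold higher in replicate 2 (2.10 to 3.41). Igf2 (ENSMUSG00000048583.12, chromosome 7, 142650766 to 142666816, minus strand), a growth factor gene, had 120 and 16 counts and was 6.77-fold higher in replicate 1 (4.01 to 12.2). The exact binomial adjusted p was 1.98e-16 for H19 and 1.86e-17 for Igf2. Of 7 tested imprinted genes, 4 were called higher in replicate 2, namely H19, Meg3, Grb10 and Kcnq1ot1, and 1 higher in replicate 1, and the Kcnq1ot1 call was lost with no filter, where Dlk1 (16 and 1 counts) and Plagl1 (25 and 1) were gained. The 18 imprinted genes together took 0.963% and 1.32% of counts, 1.37-fold higher in replicate 2 (1.20 to 1.57), but 0.729% and 0.659% when H19 was left out. With H19 the ratio was 1.10 with scaling factors from unfiltered genes and 1.13 with those from genes of mean count 10 or more. The median log2 TPM ratio of the imprinted genes, replicate 2 over replicate 1, was -0.455 (percentile 5.375 among matched random lists).

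Apolipoproteins took 0.295% and 0.332% of counts, with Apob at 46 and 32 and Apoa1 at 18 and 23, and neither of the 2 members that passed the filter was called. With no filter, Apoa2 (29 and 9 counts, exact adjusted p = 0.0286) was called higher in replicate 1 and Apom (2 and 19 counts, 0.0118) higher in replicate 2. Coagulation genes took 0.202% and 0.186%, or 0.131% and 0.166% without Fga and 0.190% and 0.118% without Kng1, with Kng1 at 5 and 24 counts and Fga at 30 and 7. These 2 were called in opposite directions with no filter, at exact adjusted p of 0.0268 and 0.00436. Complement genes had 28 and 24.7 counts, with C3 at 9 and 12. Urea cycle genes had 3 and 9.45 counts, gluconeogenesis and glycogen genes 9 and 3, amino acid catabolism genes 6 and 4, cytochrome P450 genes 3 and 16 and bile acid genes 5 and 2. Of the P450 counts in replicate 2, 13 fell on Cyp2e1, which had 0 in replicate 1, and without it the list had 3 and 3. Cps1, the entry enzyme of the urea cycle, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had no count in either library. At the set floor of 3 counts this allows shares of up to 0.00713% in replicate 1 and 0.00844% in replicate 2. Liver transcription factors had 14 and 11 counts, with Hnf4a at 3 and 3.

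The cell cycle list had reads on all 24 of its members in at least 1 library. It took 0.740% of counts in replicate 1 (95% Wilson interval 0.663 to 0.828) and 1.73% in replicate 2 (1.60 to 1.87). Mki67, the Ki-67 proliferation antigen (ENSMUSG00000031004.7, chromosome 7, 135689784 to 135716361, minus strand), had 61 and 341 counts, 6.19-fold higher in replicate 2 (4.70 to 8.27), and was the only called member of 5 tested (exact binomial adjusted p = 4.31e-53). Without Mki67 the list took 0.596% and 0.771%, 1.29-fold higher in replicate 2 (1.09 to 1.54). With scaling factors from unfiltered genes the whole list was 1.87-fold higher in replicate 2, against 2.34-fold by share. That scaling lowers the ratio of each list by the same factor, and took late erythroid genes from 1.29-fold to 1.03-fold. The 1.29-fold ratio without Mki67 would fall as far. The median log2 TPM ratio of the cell cycle list, replicate 2 over replicate 1, was 0.310 (percentile 19.11 among matched random lists). By that measure the list was not shifted towards replicate 2 beyond genes of similar mean expression. Rrm2, a subunit of ribonucleotide reductase (9 and 42 counts), and Mcm7, a subunit of the replicative helicase (7.92 and 31), did not pass the filter and were called higher in replicate 2 without it, at exact adjusted p of 0.000437 and 0.0177. Top2a had 46 and 37 counts and Birc5 had 28 and 28. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had 38.65 and 11 counts, but 5 and 10 without Hist1h2bb, at 33.65 and 1.

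Markers of the remaining blood and stromal cells had few counts, at most 39 in a list and library. Megakaryocyte and platelet genes had 39 counts in replicate 1 and 15 in replicate 2, with Itgb3 at 6 and 6 and Ppbp at 7 and 0. Macrophage genes had 14.9 and 16 counts, with C1qc at 3 and 3. Neutrophil genes had 9 and 6, with S100a8 at 3 and 3, and stem and progenitor cell genes had 9 and 9, with Kit at 1 and 2. Stellate and mesenchymal genes had 30 and 15 counts, endothelial genes 19 and 14, cytokine genes 4 and 13, cytokine receptor genes 9 and 12, with Epor, the erythropoietin receptor, at 5 and 3, and immediate early and heat shock genes 1 and 3. Mast cell and basophil markers had 0 and 1 counts and mesothelial markers 1 and 0. No read fell on the B lineage, the T and NK lineage or the cholangiocyte markers, among them Cd19, Cd79a, Cd3e, Krt7, Krt19 and Sox9. For other tissues, markers of pancreas, skeletal muscle, lung and the nervous system had no count, gut markers had 0 and 3, heart markers 0 and 1 and skin markers 1 and 0. A list with no count was not detectable above 0.00713% of mouse gene counts in replicate 1 and 0.00844% in replicate 2.

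**Figure D2:**
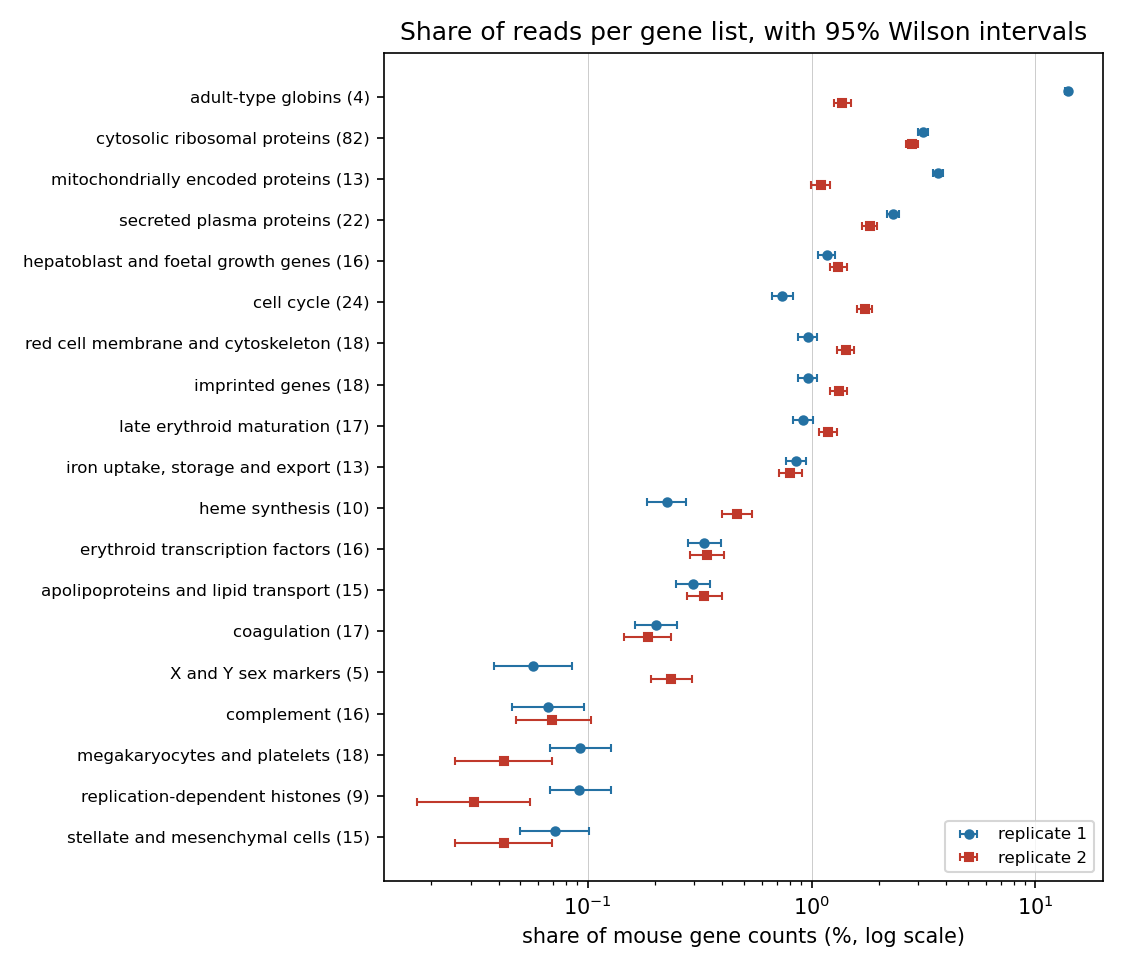
Share of mouse gene counts (horizontal, percent, log scale) of the 19 gene lists with at least 40 counts over both libraries, with the number of members in brackets; circles are replicate 1, squares replicate 2, and bars are 95% Wilson intervals. Adult-type globins lie at 13.9% and 1.37%, and mitochondrially encoded proteins at 3.68% and 1.10%.

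Mitochondrially encoded protein genes stood with the globins, at 3.68% of counts in replicate 1 and 1.10% in replicate 2, 3.34-fold higher in replicate 1 (2.99 to 3.74). With counts scaled in 7 ways, the fold of replicate 1 over replicate 2 ran from 1.60 to 4.17. Of 7 tested members, mt-Nd1, mt-Nd2, mt-Nd5 and mt-Cytb were called higher in replicate 1 by the exact binomial test, while mt-Co1 had 148 and 122 counts (1.10-fold, 0.856 to 1.40). The mt-Nd2 direction turned with the scaling from the 25 most abundant genes, and mt-Co2, mt-Co3 and mt-Atp6 share nearly all of their sequence with nuclear copies, which makes their counts uncertain. The counts of mt-Co1 and mt-Nd4 (88.9 and 73) are also uncertain, since 59.7% and 62.6% of their 36-nt stretches lie in copies that had 96.8 and 76.1 counts in replicate 1 and 0 in replicate 2. With no filter mt-Co2, mt-Atp8 and mt-Nd3 were called higher in replicate 1, but 98.1% of the stretches of mt-Nd3 lie in Gm28438, which had 92.9 and 9 counts, so its count is uncertain as well. Cytosolic ribosomal protein genes (82 members) took 3.15% and 2.82%, or 2.58% and 2.77% without Rps2, and 5 of 11 tested were called, 4 higher in replicate 1 (Rps2, Rps18, Rpl13a and Rpl36a) and Rps5 higher in replicate 2. The direction for Rps18 was among those that the 25-gene scaling turned. With no filter, 12 members were called higher in replicate 1, such as Rpl3 (117 and 1.5 counts, exact adjusted p = 5.75e-31) and Fau (74 and 3, 3.93e-17), and 15 higher in replicate 2, such as Rps3 (2 and 112, 4.60e-27) and Rpl4 (7 and 77.2, 6.00e-13), while Rps5 was lost (0.235). Reads of these genes may be shared with processed pseudogenes, which was not tested for this list. Xist, the RNA that silences an X chromosome in female cells (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), had 23 and 75 counts, 3.61-fold higher in replicate 2 (2.24 to 6.04, exact binomial adjusted p = 6.30e-08). The Y-linked Kdm5d had 1 and 4 counts, Ddx3y 0 and 3, Eif2s3y 0 and 1 and Uty 0 and 1, so Y-linked reads were present in each library, on 1 count in replicate 1.

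In further pairs of related genes, Hbb-y lay below Hbb-bt by a log2 ratio of -5.15 ± 0.70 and Hbb-bh1 by -6.66 ± 1.20, both on 12 or fewer counts per library of the embryonic gene. Hbb-bs, the other adult beta entry, was at 74113 and 11946 TPM in replicates 1 and 2, against 9249 and 7826 for Hbb-bt. These ratios therefore understate the gap to both adult entries together. Pkm over Pklr was -0.98 ± 0.36, Aldoa over Aldob -0.41 ± 0.17, on 7 or fewer counts, and Ccnd3 over Ccnd1 2.25 ± 1.70 (SD, n = 2). Hba-x had 3 and 3 counts beside the uneven Hba-a1. Other pairs had no count for a member in at least 1 library. Igf2 was at 120 and 16 counts with Igf1 at 2 and 0, Car2 at 79 and 33 with Car1 at 1 and 0, Alas2 at 15 and 15.9 with Alas1 at 0 and 2, and Slc2a1 at 10 and 4 with Slc2a2 at 2 and 0. Gata1 (19 and 2) and Bcl2l1 (13 and 7) had reads where Gata2 and Bcl2 had none, and Hnf4a (3 and 3) where Hnf4g had none. Glul had 23.4 and 0 counts with Gls2 at 1 and 0, Gys1 0 and 1 with Gys2 at 3 and 2, Hk2 1 and 0 with Gck at none, Cyp3a16 0 and 1 with Cyp3a11 at none, and Foxa3, Foxa1, Epo and Thpo had none.

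Among genes of mean count 10 or more, the replicates differed far beyond counting error. At 1 TPM or more in both libraries, 4805 genes were detected, 4628 of them protein-coding and 23 lincRNAs, but only 216 had 10 counts in both. Over the 570 genes of mean count 10 or more, the chi-square of the counts was 29.2 per degree of freedom and 64% of genes were over 2-fold apart. The spread grew with level. The mean chi-square per gene was 1.47 over 3610 genes of mean count 1 to 2.5 and 10.8 (median 6.46) over 433 genes of 10 to 25. It was 329 over the 25 genes of mean count 100 or more. Of the 207 genes that passed the count filter, 57 (27.5%) were called by the exact binomial test, 27 higher in replicate 2 and 30 higher in replicate 1, and 69 had an unadjusted p under 0.05. Without the filter the split was 215 and 173 of 10239 genes, and 44 of the 57 kept their call; the 13 lost had been higher in replicate 2. Among the called genes with the largest TPM ratios, Set, Dek, Hspa8 and Eef1a1 were higher in replicate 2 (75.6, 70, 146 and 255 counts against 11, 17, 21.5 and 53.1), and Rps2, Rpl13a, Cdk4 and Rbm5 higher in replicate 1 (242, 99.8, 91 and 34 against 15.7, 9.70, 39 and 12), though Cdk4 turned with the 25-gene scaling. Among further genes of high mean TPM, mt-Rnr2 had 580 and 125 counts, mt-Rnr1 328 and 139 and Hsp90ab1 175 and 53. Across 10325 genes with TPM above 0 in either library, Pearson's r of log2(TPM + 1) was -0.03 and Spearman's rho 0.02, which describes genes and not independent replicates. Over the genes above 0 in both libraries they were 0.54 and 0.50, and over all gene entries 0.57 and 0.57. Of 10323 genes with counts in either library, 4811 had counts in both, and keeping genes with reads in only 1 library lowers r. No value under counting error alone was computed, so these correlations do not measure the disagreement beyond it. The common biological coefficient of variation from edgeR was 0.497 over the 207 filtered genes, but 1.09 over 573 genes of mean count 10 or more. These values describe the 2 libraries, and their differences cannot be assigned to any condition.

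Leading transcripts were compared in 31 genes of the pairs and transcription factor lists with a mean of 5 TPM or more. Each had 2 or more transcripts and reads in both libraries. Alb, Afp, Hbb-bt, Klf1 and E2f4 were not among the 31, so the comparison does not cover every gene of those lists at that level. Of the 31, 10 had the same leading transcript in both libraries, and the leading share differed by a median of 62.5 percentage points. Of the 5 among these 31 with 10 or more counts in both libraries, 1, Car2, had the same leading transcript. The 2503-nt Igf2 transcript held 0% of the gene's TPM in replicate 1 and 71.2% in replicate 2, on 120 and 16 counts. The 2037-nt Alas2 transcript held 100% of the gene's TPM in replicate 1 and 14.2% in replicate 2, on 15 and 15.9 counts. Car2 kept its 1788-nt transcript at 98.3% and 100%.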

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

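The test of shallow sequencing was chosen after the count totals had been seen.

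Reads on phiX174, a bacteriophage genome used as a sequencing control, are data outside the main measurement and lay above the limit that a count of 0 allows. Replicate 1 had 21233 such counts (33.4% of all counts, 95% Wilson interval 33.0 to 33.7) and replicate 2 had 17140 (32.4%, 32.0 to 32.8). The gene tables held few counts in all, 63611 and 52862. Sequencing of few reads may account for this, but the signal track listed in the deposited notes with the lowest size per counted read took 684 bytes for each counted read, and how many bytes a track needs per read is not known here, so that explanation stays open. No biological explanation was tested for this pattern.

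Entries with a number as identifier also held reads above that limit, 274.79 counts in replicate 1 over 224 entries and 185.82 counts in replicate 2 over 115 entries. The 96 ERCC spike-in entries had no count, which allows up to 3 counts, a share of 0.00472% and 0.00568% of all counts, although the labels name a spike-in reference.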

How the results depend on the processing

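The following alternatives were chosen after the data were seen: mean count of 10 or more, all gene entries, genes above 0 in both libraries, expected counts in place of TPM, TPM over mouse genes only, random lists of all protein-coding genes, the list and called-gene directions under 7 scalings, and lists without their leading or most influential member. No paired analysis was possible because the series has 1 group. Of 921 values recomputed with both libraries kept, 659 stayed within a limit set for each kind of value, 254 moved and 8 changed sign. The limit was a fixed fold for numbers of genes, a fixed difference for the coefficient of variation and a Fisher interval over genes for correlations. For other values it was a spread. A spread of 2 libraries can exceed the mean, as for adult-type globins (114054 ± 132256 TPM, SD), so staying within it says little there. Detection at 1 TPM in both (4805 genes) came to 216 with 10 or more counts in both and 33024 by posterior mean TPM, in which entries without reads hold values. Pearson's r of -0.03 became -0.17 with a pseudocount of 0.1, 0.12 with 5, 0.85 by posterior mean TPM, 0.10 over protein-coding genes, 0.54 over genes above 0 in both, 0.57 over all gene entries, -0.19 over genes of mean count 10 or more (where rho was -0.024) and 0.28 on counts. The value of r depended on the genes and the scale used. By posterior mean TPM, genes with reads in only 1 library also hold a value in the other. Gls2 (1 and 0 counts) was at 18.1 and 17.4 and Glul (23.4 and 0) at 20.8 and 9.55. This can raise r, so 0.85 does not measure agreement of the reads alone. The coefficient of variation of 0.497 was 0.868 without a filter, 1.38 over the 25 genes of mean count 100 or more, 0.937 over the same 25 genes from the median DESeq2 dispersion and 1.09 at a mean count of 10 or more. Genes higher in replicate 2 (27) and in replicate 1 (30) numbered 215 and 173 without a filter and 175 and 153 at a mean count of 10 or more.

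Summed TPM by posterior mean was 421 for red cell membrane, 309 for late erythroid, 321 for hepatoblast, 581 for plasma protein, 301 for cell cycle, 469 for imprinted, 1179 for mitochondrial and 2729 for ribosomal protein genes. Over protein-coding genes only it was 13749 for red cell membrane, 8794 for late erythroid, 19458 for plasma protein, 7506 for cell cycle, 2562 for imprinted and 79065 for ribosomal protein genes. Without globins and mitochondrial genes it was 6631 for hepatoblast, 12609 for plasma protein and 51906 for ribosomal protein genes, and plasma protein genes were at 10916 without mitochondrial genes alone. Over mouse genes only it was 7088 for hepatoblast, 13270 for plasma protein, 6562 for imprinted and 54228 for ribosomal protein genes. Removing entries raises the TPM of every entry kept, by construction. The imprinted sum over protein-coding genes only nevertheless fell from 5230, since noncoding members such as H19 (2495 TPM) were removed from it. The pair Aldoa over Aldob turned to 0.52 by posterior mean TPM, and the cause was not tested.

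With either replicate left out, the other library is the value, which says nothing of stability. Afp over Alb ranged from -1.66 to -1.06. Summed TPM ranged from 20535 to 207573 for adult-type globins, 4514 to 9956 for red cell membrane, 3826 to 5566 for late erythroid, 5006 to 6287 for hepatoblast, 10380 to 10734 for plasma protein, 2494 to 5410 for cell cycle, 4343 to 6118 for imprinted, 8130 to 31902 for mitochondrial and 39673 to 46553 for ribosomal protein genes. Scaling from the 25 genes of mean count 100 or more moved every log2 ratio of replicate 2 over replicate 1 by 1.16 and turned 9 of the 57 called genes; the other scalings moved it by -0.22 to 0.10 and turned none. Of 19 lists, 10 kept their direction under all 7 scalings. The depth leaves lists of under 40 counts with wide intervals, such as 1.81 to 33.8 for the ratio of cytochrome P450 genes, and 0.159 to 8.85 without Cyp2e1.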

Other observations

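The tests of shared reads, of clumped amplification and of the level of the nuclear copies, and the rule that picked genes present in 1 library, were chosen after the values had been seen. The test of shared reads replaced an earlier one on genes with whole-number counts. The tests of GC content and length and of shared sequence in nuclear copies of mitochondrial genes were written before their results were seen.

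Several genes were abundant in 1 library and nearly absent from the other. Galnt13, which encodes a glycosyltransferase (chromosome 2, 54436317 to 55118309), had 316 counts in replicate 1 and 0 in replicate 2. Pacs2 had 212 and 0 counts. Coro2a (chromosome 4, 46536937 to 46602202) had 1 and 146 counts, 162-fold higher in replicate 2 (28.6 to 6428). The ribosomal protein genes Rpl3 and Rps3 went opposite ways, with 117 and 1.5 counts for Rpl3 and 2 and 112 for Rps3. Gm15564, an antisense gene on chromosome 16, had 1 and 168 counts, and its reads cannot be assigned to a strand. The unmatched entry ENSMUSG00000089855.1 had 323 and 0 counts.

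Among lists, the median log2 ratio of replicate 2 over replicate 1 of the adult-type globins was -4.28 (percentile 0.69 among 10000 matched random lists), of the mitochondrially encoded proteins -2.28 (percentile 0.08) and of the megakaryocyte genes -2.11 (percentile 1.07). The X and Y markers, of which the Y genes had 4 or fewer counts per library, were at 4.66 (percentile 97.8). The megakaryocyte genes also had few counts, 7 or fewer per gene and library, and 8 of the 13 with reads had them in only 1 library. These percentiles describe the 2 libraries.

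The difference between the libraries beyond counting error had 3 technical explanations tested. A smooth trend on GC content and transcript length explained 9.73% of the variance of the log2 count ratio over 566 genes, and 325 genes were called after its removal against 321 before, which argues against it as the whole cause. Of 146 genes that share no 36-nt stretch with another gene, 47.9% were called, against 59.8% of 420 genes that share one, so shared reads may add to the difference but do not account for all of it. Amplification in clumps of a constant size would give about the same chi-square per gene at every level, but it was 5.99 times as high at a mean count of 50 to 100 as at 10 to 25 (95% bootstrap interval 4.37 to 7.84). Clumps of unequal size, losses of molecules before amplification and a biological difference between the embryos or pools stay open and untested.

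The mitochondrial genes mt-Atp6 and mt-Co3, which are usually abundant, had almost no counts here, with 0 and 0 for mt-Atp6, and for mt-Co3 0.46 and 0.02. A candidate explanation is that their reads were assigned to nuclear copies, since 99.5% of the 36-nt stretches of mt-Atp6 occur in Gm10925 (chromosome 1, 24613974 to 24614651), which had 40 and 1 counts, and 99.9% of those of mt-Co3 in Gm28437 (chromosome 1, 24613189 to 24613971), which had 111 and 3.98. Shared sequence makes this possible, and in replicate 1 the genes with their copies had 58.7 counts per kb for mt-Atp6 and 142 for mt-Co3, where 6 mitochondrial protein genes with under 20% of stretches in other genes had 55.9 or more. In replicate 2 they had only 1.47 (95% Poisson interval 0.0372 to 8.18) and 5.10 (1.39 to 13.1), against 14.0 to 48.2 for 5 of those genes and 1 count in all for the shorter mt-Atp8, so the counts of that library leave the explanation open. The neighbouring mt-Co2, with 100% of its stretches in nuclear copies, kept 350 counts in replicate 1 and had 0 in replicate 2, where its copies had 34, so the assignment was not uniform.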
